A study of Mus musculus with 12 samples.

How the data were processed

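Small intestine was taken from mice with an intestinal epithelial Piezo1 knockout (CKO) and from floxed controls (flox), each without injury and with NEC. RNA was isolated with Trizol reagent and libraries were made with the NEBNext Ultra II RNA kit, per the labels. The aligner, the read counter, the genome build and the age of the mice are not given in the sources used here. The values are deposited FPKM in 2 tables, 1 for each condition, with 6 libraries and 54532 genes each, and with gene lengths. The coordinates of 53499 genes (98.3% of those matched) were identical to those of GENCODE M21, which is on GRCm38.

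FPKM times gene length fell on whole multiples of a single step in each library, for 100% of values within a tolerance of 0.05, and dividing by the step gave the number of reads per gene. Whether the authors counted reads or fragments is not given in the sources used here, and reads is the word used below. The recovery was tested on 12 simulated libraries and returned the exact number for 100% of genes. Depth was 13057724 to 16821130 reads per library. The library sizes behind the deposited FPKM were 0.957 to 1.06 times the recovered totals in the NEC table and 0.853 to 1.00 times in the control table. Divided by median-of-ratios size factors, they were steady within the NEC table when the factors came from its 6 libraries (1.01 to 1.02), and steady within the control table when the factors came from all 12 libraries (1.00 to 1.01). The 2 tables were therefore scaled separately, and the deposited NEC values sit on average 0.15 log2 above a scaling shared by all 12 libraries.

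Genotypes were compared within each table. FPKM values plus 1 were put on the log2 scale. Genes with an FPKM of at least 1 in at least 3 of the libraries fitted were tested with limma 3.58.1 in R 4.3.3, with moderated statistics and a mean-variance trend, and p-values were adjusted by Benjamini-Hochberg at 0.05 with no fold threshold. Each genotype comparison used the 6 libraries of its condition, and the interaction used all 12. The median standard error over genes was 0.15 log2 in NEC, 0.16 in control and 0.23 in the interaction. On data simulated with 200 changed genes, limma called 71.6% of the 2-fold changes in NEC, 62.7% in control and 49.3% in the interaction, and 93.9%, 89.4% and 87.9% of the 4-fold changes, with 3, 9 and 6 false calls. The changed genes had a mean FPKM of at least 5 and were shifted on the scale of log2 FPKM plus 1. These shares therefore do not cover genes at lower FPKM. The groups, comparisons, tests, filters and 38 gene lists were chosen before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated per list. For each list the members past the threshold were counted over all genes and adjusted over the list alone. The score of a list in a library is the median over its members fitted of log2 FPKM plus 1, less the mean of the flox group of that condition. Other work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

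Named genes were chosen by a rule fixed beforehand. Piezo1 and the 4 Camk2 genes were always named. Each comparison added the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups do not overlap, leaving out predicted gene models and immunoglobulin or T cell receptor segments. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were added as values only. Each list past its test added up to 4 members with the smallest p. For 4 lists named for the study's subject (Ca2+ and CaMKII signalling, inflammatory cytokines, junctions and cell death) the 2 members with the smallest p were added where the list did not pass. Where the report compares NEC with control, the named genes are those the same rule gives on jointly rescaled values, and their levels are given without a test. The report names some of the genes the rule gives, and a few of them are not reported here.

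NEC was not tested against control on deposited values as a main result, because condition and table are the same split and the tables were scaled separately. The test planned for a reversal of the NEC change by the knockout was not run on them for the same reason. Both were run on reads rescaled over all 12 libraries by median-of-ratios factors, an addition described among the other observations. The test of NEC against control was repeated on deposited values only as an alternative to that addition. Alternatives to the genotype tests covered the pseudocount (0.1), no filter and a stricter filter (mean FPKM of at least 5), equal library medians, quantile normalization, the replicate number as a block, no variance trend, array weights, all 4 groups in 1 fit, the estimated correlation and leaving out each library in turn. Alternatives added after the data were seen were limma-voom on recovered reads (at least 10 reads in at least 3 libraries), protein-coding genes alone, sex or the mitochondrial read share as a covariate, and removal of a trend on gene length. Replicate numbers were checked for pairing between groups. The correlations of libraries with the same number ran from -0.12 to 0.36. The highest was between flox control library 3 and CKO control library 3. These libraries also shared high Paneth scores (1.88 and 0.92) and low cell cycle scores (-0.60 and -0.67). The other same-number pairs of the control groups had 0.11 and -0.03, which gave no ground for a paired main test over all libraries.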

Results

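RNA from the small intestine of C57BL/6J mice was sequenced in 12 libraries, 3 in each of 4 groups. The groups crossed 2 genotypes with 2 conditions. CKO mice were labelled as lacking Piezo1, a mechanically gated channel that lets Ca2+ into the cell, in intestinal epithelial cells, and flox mice were their floxed controls. Each genotype was sampled without injury (control) and after necrotizing enterocolitis (NEC), an inflammatory necrosis of the newborn bowel, had been induced. The study's title concerns Piezo1 in NEC and signalling through Ca2+ and its kinase CaMKII. The age of the mice is not given in the sources used here. Nothing in the labels says that the libraries came from separate mice, so every p-value here measures the spread between libraries. The deposited FPKM values of each library were whole multiples of a single step, which gave back 15438958, 14725734 and 16202266 reads for the flox control libraries, 15902125, 15945424 and 16821130 for the CKO control libraries, 13057724, 14273692 and 13525300 for the flox NEC libraries and 15943592, 15022468 and 14795815 for the CKO NEC libraries. Xist and the Y-linked genes marked 1 flox control, 2 flox NEC and 1 CKO NEC library as female and the others as male. The first principal component held 59.5% of the variance and parted NEC (scores of 28.1 to 52.3) from control (scores of -50.0 to -36.8). CKO NEC library 3 had the lowest score among the NEC libraries, with the other 5 between 41.4 and 52.3. Group values below are means ± SD of deposited FPKM (n = 3 libraries), and changes are log2 ratios of FPKM plus 1.

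Piezo1 (ENSMUSG00000014444, chromosome 8, 122481698 to 122551329 on GRCm38) was read in all 12 libraries. In control tissue it stood at 1.38, 1.44 and 1.09 FPKM in the flox libraries and at 1.71, 1.03 and 0.926 FPKM in the CKO libraries, with overlapping values (log2 change of -0.06 ± 0.19 SE, adjusted p = 0.846). The uninjured libraries thus do not show the loss the labels give, and whole tissue also holds cells other than epithelium. In NEC tissue it stood at 7.38, 7.23 and 6.76 FPKM in the flox libraries and at 5.38, 5.58 and 3.23 FPKM in the CKO libraries, lower in 3 of 3 CKO libraries (log2 change of -0.53 ± 0.18 SE). That difference did not pass the threshold over all genes tested (adjusted p = 0.840), and without CKO NEC library 3 it was -0.32. The genotype difference in NEC less that in control was -0.46 ± 0.25 SE (adjusted p = 0.325). Of the genes for the CaMKII subunits, Camk2g (ENSMUSG00000021820) stood at 8.80 ± 2.24 and 7.07 ± 0.758 FPKM in flox and CKO control tissue and at 10.2 ± 0.557 and 9.16 ± 1.05 FPKM in flox and CKO NEC tissue. Camk2d (ENSMUSG00000053819) stood at 5.02 ± 1.30 and 5.86 ± 1.25 FPKM in control and at 9.75 ± 0.330 and 9.12 ± 1.01 FPKM in NEC, again flox first. Camk2b (ENSMUSG00000057897) stood at 2.77 ± 0.759 and 3.39 ± 1.96 FPKM in control and at 3.64 ± 0.264 and 4.14 ± 0.195 FPKM in NEC. None of these 3 genes passed the threshold between genotypes in either condition (adjusted p of 0.840 to 0.882 in NEC and 0.407 to 0.781 in control). Camk2a (ENSMUSG00000024617) lay under 1 FPKM in every group mean, between 0.508 ± 0.193 and 0.890 ± 0.130 FPKM, and was not tested.

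**Figure D1:**
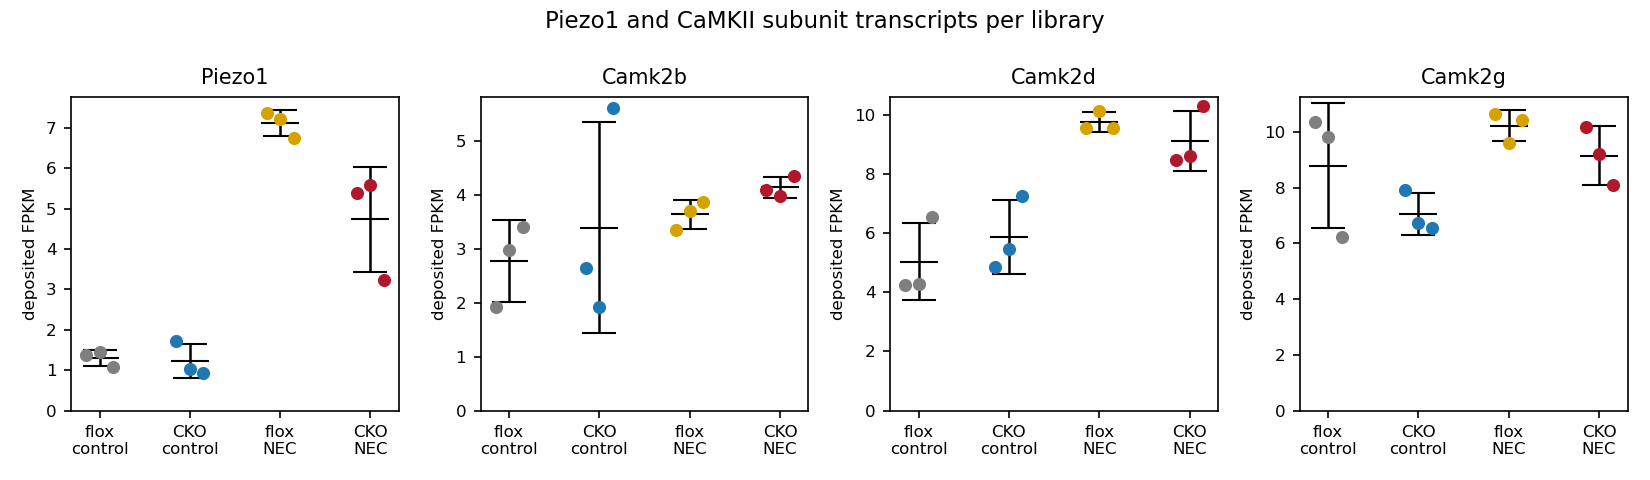
Deposited FPKM of Piezo1 and of 3 CaMKII subunit genes in the 12 libraries, by genotype and condition, with points for libraries and bars for the mean and SD. Piezo1 sits between 3.23 and 5.58 FPKM in the CKO NEC libraries and between 6.76 and 7.38 FPKM in the flox NEC libraries, and the 2 conditions come from tables scaled separately.

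The comparison of CKO with flox in NEC tissue asks what goes with the CKO genotype in the injured bowel. Transcripts of Paneth cells, goblet cells, smooth muscle and matrix stood lower in CKO tissue, and interferon-stimulated transcripts stood higher, but no single gene passed the threshold. The Paneth cell markers, which are antimicrobial products of the crypt base, were below flox in 11 of 11 tested members with a median of -0.94. The alpha-defensin Defa24 stood at 175 ± 53.7 FPKM in CKO against 272 ± 13.99 in flox, and the antimicrobial ribonuclease Ang4 at 1.76 ± 0.457 against 3.62 ± 0.379. As a list they fell (adjusted p = 8.89e-07), a call lost with an estimated correlation (adjusted p = 0.570 with an estimated correlation). Goblet cell markers were below flox in 8 of 9 members (median of -0.48). Agr2, a chaperone of mucin folding, stood at 62.6 ± 35.3 against 94.3 ± 12.4 FPKM, and the secreted goblet product Clca1 at 45.5 ± 34.4 against 77.5 ± 17.9. The adjusted p of the goblet list was 0.00613, and 0.603 with an estimated correlation. Enteroendocrine markers were below flox in 8 of 12 members (median of -0.11, adjusted p = 0.0208, and 0.570 with an estimated correlation), among them the granule proteins Chga (9.11 ± 2.06 against 15.3 ± 3.08 FPKM) and Chgb (15.6 ± 2.40 against 27.8 ± 4.93 FPKM). The Paneth list was not lower in each CKO library: its scores were 0.17, -1.26 and -1.55 in CKO NEC libraries 1 to 3, and the lysozyme gene Lyz1 stood at 40.99, 11.5 and 6.54 FPKM against 34.9, 34.4 and 33.7 in flox. The goblet scores were -0.89, 0.21 and -0.52 in CKO and -0.29, -0.12 and 0.35 in flox. The Paneth median was -1.54 without CKO NEC library 1 and -0.63 without CKO NEC library 3. The goblet call was lost without CKO NEC library 1 (median of -0.10, adjusted p = 0.245), CKO NEC library 3 (-0.47, adjusted p = 0.0664) or flox NEC library 3 (-0.32, adjusted p = 0.267). The enteroendocrine call was lost without CKO NEC library 1 (-0.16, adjusted p = 0.0875) or flox NEC library 3 (-0.0099, adjusted p = 0.209), and its median was -0.21 without CKO NEC library 3 and -0.19 without flox NEC library 1.

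Transcripts of the cells under the epithelium were also lower in CKO NEC tissue. Fibroblast and matrix genes were below flox in 12 of 12 members (median of -0.42), with the matrix protein Fn1 at 29.3 ± 10.5 against 49.7 ± 6.93 FPKM and the fibroblast receptor Pdgfra at 13.3 ± 1.99 against 19.1 ± 2.46. Smooth muscle genes were below flox in 10 of 10 members (median of -0.83), with Des, the muscle filament desmin, at 72.5 ± 40.6 against 119 ± 19.6 FPKM. Endothelial markers such as Kdr and Pecam1 had a median of -0.17, enteric neuron and glia markers one of -0.44, and macrophage and monocyte markers such as C1qc and Mrc1 one of -0.22. These 5 lists fell at adjusted p of 8.89e-07, 2.11e-05, 0.00216, 0.00739 and 9.24e-04 in that order, and each had an adjusted p of 0.570 with an estimated correlation. CKO NEC library 3 held the lowest smooth muscle score, -1.91 against -0.20 and -0.35 in the other CKO NEC libraries, and without it the smooth muscle median was -0.25 and the fibroblast median -0.18, which was -0.28 without flox NEC library 1. The endothelial call was lost without CKO NEC library 3 (-0.10, adjusted p = 0.0664; -0.28 without CKO NEC library 1), the macrophage call without CKO NEC library 1 (-0.13, adjusted p = 0.142) and the neuronal call without CKO NEC library 3 (-0.14, adjusted p = 0.236) or flox NEC library 1 (-0.24, adjusted p = 0.0786).

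Interferon-stimulated genes, which are antiviral response genes, were above flox in 12 of 12 members (median of 0.63, adjusted p = 5.45e-04, and 0.582 with an estimated correlation). Ifit1 stood at 14.5 ± 9.26 FPKM in CKO against 7.47 ± 2.34 in flox. CKO NEC library 2 carried most of that difference, with Ifit1 at 24.8 FPKM beside 6.82 and 11.8 in the other CKO NEC libraries. Without that library the interferon call was lost (0.05, adjusted p = 0.681), and without CKO NEC library 1 the median was 0.96. Cell cycle genes were above flox in 20 of 21 members (median of 0.16), cell death genes in 17 of 23 (median of 0.18) and nuclear oxidative phosphorylation genes in 21 of 21 (median of 0.09). The inflammasome adaptor Pycard stood at 29.9 ± 2.51 against 21.7 ± 2.80 FPKM, and Birc5, which acts in cell division, at 8.60 ± 1.12 against 6.84 ± 0.643. These 3 lists rose at adjusted p of 3.80e-04, 0.00416 and 0.0166, against adjusted p of 0.570, 0.570 and 0.765 with an estimated correlation. The cell cycle call was lost without CKO NEC library 1 (0.11, adjusted p = 0.139), with medians of 0.28 without CKO NEC library 3 and 0.09 without flox NEC library 3. The cell death call was lost without CKO NEC library 2 (0.14, adjusted p = 0.0511; 0.09 without CKO NEC library 3), and the oxidative phosphorylation call without CKO NEC library 1 (0.02, adjusted p = 0.617), CKO NEC library 3 (0.05, adjusted p = 0.179) or flox NEC library 3 (0.07, adjusted p = 0.0692; 0.21 without CKO NEC library 2).

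Mechanosensitive channels, Piezo1 and the channel kinase Trpm7 among them, were below flox in 8 of 10 members (median of -0.22). Genes of Ca2+ and CaMKII signalling were below flox in 23 of 30 members (median of -0.08), and YAP target and injury-response genes such as Cyr61 and Ereg in 9 of 12 (median of -0.13). These 3 lists fell at adjusted p of 0.00312, 0.0390 and 0.0271, and each had an adjusted p of 0.570 with an estimated correlation. Without CKO NEC library 3 the mechanosensitive median was -0.11 and the YAP call was lost (-0.09, adjusted p = 0.465). Without flox NEC library 3 the YAP (-0.13, adjusted p = 0.108) and Ca2+ calls (-0.05, adjusted p = 0.281) were lost, and without CKO NEC library 1 the Ca2+ call was (-0.05, adjusted p = 0.553). The YAP median was -0.23, -0.21 and -0.22 without CKO NEC library 1, CKO NEC library 2 and flox NEC library 2. Tight and adherens junction genes had a median of -0.02 (adjusted p = 0.793), with the scaffold Tjp1 at 20.4 ± 1.63 against 25.9 ± 1.88 FPKM. Toll-like receptor and NF-kappaB signalling genes had one of 0.03 (adjusted p = 0.704). Too few inflammatory cytokine genes were expressed for a list test; Il1a stood at 0.613 ± 0.341 against 1.12 ± 0.526 FPKM and Ccl20 at 1.03 ± 0.489 against 1.44 ± 0.504.

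By limma, 0 of 13673 genes tested in NEC passed the adjusted threshold, 599 had an unadjusted p under 0.05 (4.38% of those tested), and limma-voom on the recovered reads also called 0. The CKO and flox values of 1500 genes (10.97%) did not overlap, where chance gives 10%. The genes with the smallest p that stood higher in CKO were Mir7213, Lsmem2, Ccl17, Hdhd3 and H2-Q2, and those that stood lower were Mir6942, Clps, Ldlrad4, Ang4 and Chgb, at adjusted p of 0.485 to 0.840. Mir7213 was listed at 0 in the flox NEC libraries and at 1.04, 1.12 and 1.24 FPKM in the CKO NEC libraries. Its values rest on very few reads. The chemokine Ccl17 stood at 3.52 ± 0.679 against 0.785 ± 0.659 FPKM, and Clps, the pancreatic colipase, at 2.15 ± 0.472 against 5.54 ± 1.10. Of 30 lists tested, 4 rose and 11 fell, and 0 did so with an estimated correlation. When adjusted over the list alone, 1 Paneth and 1 enteroendocrine marker passed, and 0 did over all genes. In 4 lists that did not pass (enterocyte, hypoxia and glycolysis, immediate early and proximal intestine genes) the median, the mean and the direction of the test differed in sign. Of the 15 lists past the threshold, 4 (Paneth, smooth muscle, fibroblast and mechanosensitive) stayed past the threshold without any one library.

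**Figure D2:**
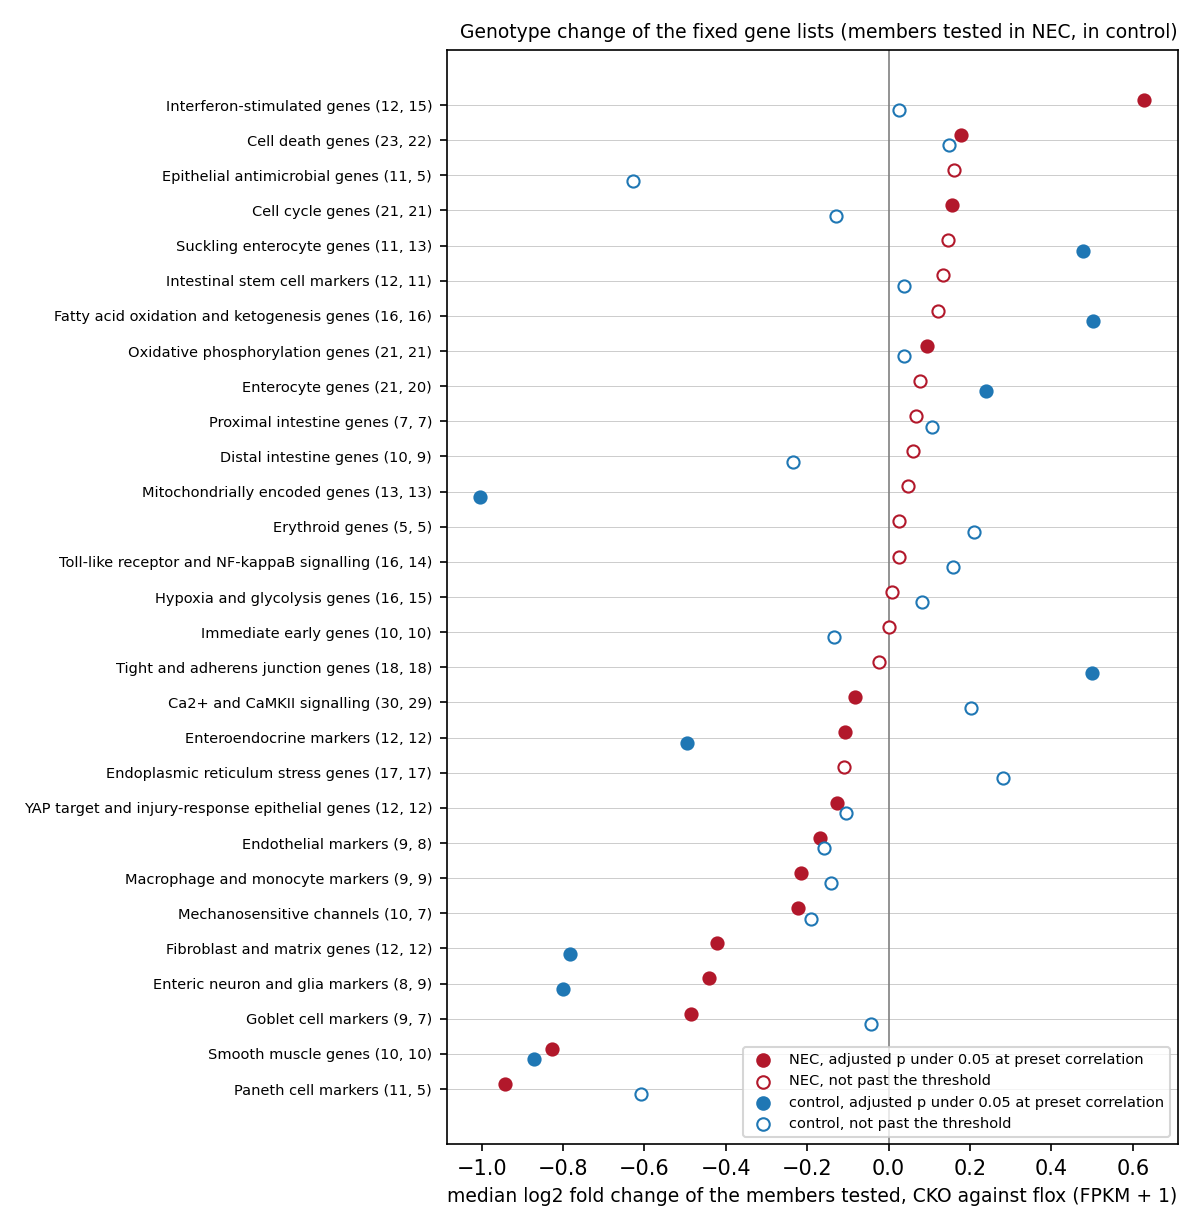
Median log2 change of each fixed gene list tested in both conditions, CKO against flox, in NEC (red) and in control (blue), with filled points for adjusted p under 0.05 at the preset correlation. Paneth cell markers have the lowest median in NEC (-0.94) and mitochondrially encoded genes the lowest in control (-1.004).

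The comparison of CKO with flox in uninjured tissue asks what goes with the CKO genotype without injury, in libraries whose Piezo1 values overlapped. Transcripts encoded by the mitochondrial genome stood lower in CKO tissue, together with those of smooth muscle, matrix and the enteric nervous system. Transcripts of absorptive enterocytes, of cell junctions and of fatty acid oxidation stood higher. The mitochondrially encoded genes were below flox in 13 of 13 members (median of -1.004, adjusted p = 3.42e-09, and 0.752 with an estimated correlation). The complex I subunit mt-Nd4 stood at 3456 ± 105 FPKM in CKO against 7002 ± 809.6 in flox, and the cytochrome oxidase subunit mt-Co2 at 775 ± 149 against 1936 ± 517. Mitochondrially encoded transcripts took 6.03% ± 0.843 of reads in CKO control libraries and 12.8% ± 1.62 in flox control libraries, against 4.09% ± 0.538 and 4.05% ± 0.407 in CKO and flox NEC libraries (SD, n = 3). Nuclear genes of oxidative phosphorylation had a median of 0.04 (adjusted p = 0.937).

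Tight and adherens junction genes were above flox in 15 of 18 members (median of 0.50, adjusted p = 6.40e-04), among them the pore-forming claudin Cldn2 (172 ± 17.6 against 81.8 ± 12.9 FPKM), occludin, Ocln (53.3 ± 5.23 against 26.5 ± 5.28), and beta-catenin, Ctnnb1 (204 ± 28.7 against 95.9 ± 31.8). Fatty acid oxidation and ketogenesis genes were above flox in 15 of 16 members (median of 0.50, adjusted p = 0.00102), with the mitochondrial trifunctional enzyme Hadha at 49.9 ± 4.12 against 27.03 ± 4.77 FPKM and the lipid droplet protein Plin2 at 213 ± 12.7 against 133 ± 23.3. Both lists had an adjusted p of 0.752 with an estimated correlation. Enterocyte genes were above flox in 14 of 20 members (median of 0.24), with Apob, the carrier protein of chylomicrons, at 327 ± 37.1 against 166 ± 34.7 FPKM. Suckling enterocyte genes, which serve milk digestion and uptake, were above flox in 12 of 13 (median of 0.48), with Fcgrt, the receptor for maternal IgG, at 1213 ± 207 against 767 ± 272. The adjusted p was 0.0480 for both enterocyte lists, and 0.891 and 0.752 with an estimated correlation. The enterocyte call was lost without CKO control library 3 (0.14, adjusted p = 0.433), flox control library 1 (0.17, adjusted p = 0.0839) or flox control library 3 (0.41, adjusted p = 0.187), and the suckling call without CKO control library 3 (0.50, adjusted p = 0.156) or flox control library 1 (0.42, adjusted p = 0.0839).

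Fibroblast and matrix genes were below flox in 12 of 12 members in control (median of -0.78), with the collagen Col3a1 at 34.3 ± 16.5 against 68.98 ± 20.8 FPKM. Smooth muscle genes were below flox in 10 of 10 (median of -0.87), with Tagln, an actin-binding protein of smooth muscle, at 1.04 ± 0.257 against 2.10 ± 0.0552. CKO control library 2 held the lowest smooth muscle score (-1.82, against -0.32 and -0.38 in the other CKO control libraries), and without it the smooth muscle median was -0.38. Enteric neuron and glia markers were below flox in 8 of 9 members (median of -0.80), while the receptor Ret stood at 28.6 ± 0.912 against 16.1 ± 6.20 FPKM. Enteroendocrine markers were below flox in 9 of 12 (median of -0.49), such as the peptide hormone genes Pyy (60.8 ± 4.12 against 97.1 ± 26.03) and Sct (56.8 ± 9.44 against 87.3 ± 21.4). These 4 lists fell at adjusted p of 2.45e-04, 6.40e-04, 0.00350 and 0.0156, and each had an adjusted p of 0.752 with an estimated correlation. The enteroendocrine call was lost without CKO control library 2 (-0.27, adjusted p = 0.0767) and the neuronal call without flox control library 3 (-0.80, adjusted p = 0.0555), and the neuronal median was -0.49 without CKO control library 2. Genes of Ca2+ and CaMKII signalling were above flox in 22 of 29 members without passing (median of 0.20, adjusted p = 0.154), with the calcineurin subunit Ppp3r1 at 36.3 ± 4.70 against 21.1 ± 4.53 FPKM. Cell death genes did not pass either (median of 0.15, adjusted p = 0.588), with Bax at 47.1 ± 9.53 against 85.7 ± 15.2 FPKM and Casp9 at 10.002 ± 1.18 against 5.82 ± 0.342. Interferon-stimulated genes (0.02, adjusted p = 0.878) and macrophage and monocyte markers (-0.14, adjusted p = 0.266) did not pass. The cytokine Lif stood at 2.83 ± 0.235 against 3.45 ± 1.27 FPKM and Il1a at 1.03 ± 0.296 against 1.80 ± 0.414.

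By limma, 1 of 13300 genes tested in control passed the threshold, while 3849 had an unadjusted p under 0.05 (28.9%; 2439 higher and 1410 lower in CKO) and limma-voom on the recovered reads called 23. The gene that passed was Gm25637 (ENSMUSG00000088154, chromosome 4, 41050220 to 41050326), a small nuclear RNA gene of 107 bases, singled out after its values were seen. It stood at 4.32, 6.32 and 8.42 FPKM in the flox control libraries, which is few reads for a gene of that length, and was listed at 0 in the 9 other libraries. The next adjusted p was 0.0547, shared by 295 genes. Among the genes with the smallest p, Hnf4g, an enterocyte transcription factor, stood at 41.4 ± 2.67 FPKM in CKO against 14.2 ± 2.67 in flox and Pigt, which attaches lipid anchors, at 43.8 ± 1.26 against 22.5 ± 1.76. The long noncoding RNA Fendrr stood at 9.35 ± 1.197 against 22.2 ± 1.75 FPKM and the complement protein Cfp at 2.25 ± 0.433 against 6.14 ± 1.11. Narf, Slc10a5 and Sacm1l also stood higher and Mir7-1, Hist3h2ba and Mapk1ip1 lower. The CKO and flox values of 4591 genes (34.5%) did not overlap, where chance gives 10%. Of 30 lists tested, 4 rose and 5 fell, and 0 did so with an estimated correlation. When adjusted over the list alone, all 13 mitochondrially encoded genes fell, 10 junction, 7 enterocyte and 7 fatty acid oxidation genes rose, and 5 neuronal or glial markers fell while Ret rose; 0 of these passed over all genes. In 4 lists that did not pass (B and plasma cell, stem cell, goblet cell and oxidative phosphorylation) the median, the mean and the direction of the test differed in sign. The number of genes past the threshold was 830 without flox control library 3 and 0 without any other single library, and it ran from 0 to 2200 over 20 alternatives.

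**Figure D3:**
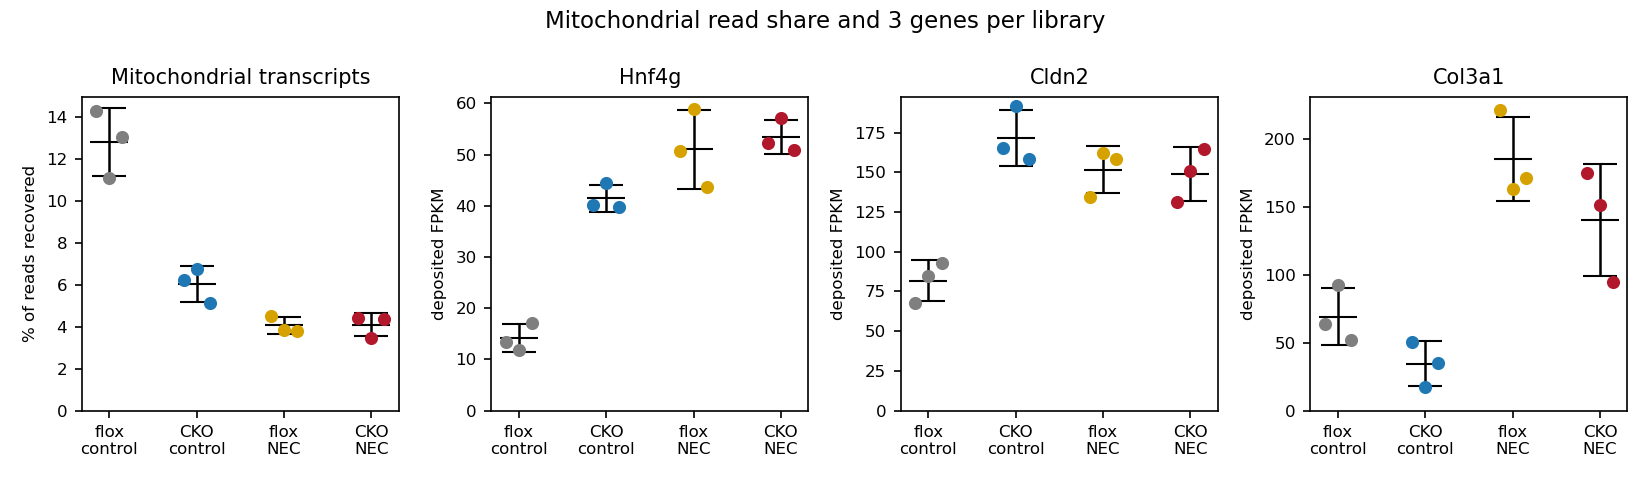
Percentage of recovered reads on mitochondrially encoded genes, and deposited FPKM of Hnf4g, Cldn2 and Col3a1, in the 12 libraries, with points for libraries and bars for the mean and SD. In control tissue Hnf4g averages 41.4 FPKM in CKO and 14.2 FPKM in flox libraries, while in NEC tissue it averages 53.5 and 51.0 FPKM.

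The interaction of genotype and NEC asks whether the genotype difference itself differed between injured and uninjured tissue. Junction genes and Hnf4g stood higher in CKO than in flox tissue without injury but not in NEC, and mitochondrially encoded transcripts stood lower in CKO tissue without injury but not in NEC. Of 14808 genes tested, 31 had a more positive and 150 a more negative genotype difference in NEC. The junction list fell in this test (median of -0.50, 15 of 18 members below 0, adjusted p = 0.00131, and 1.00 with an estimated correlation). Its members Cldn2 (interaction of -1.09 ± 0.21 SE), Ocln (-1.06 ± 0.22) and Tjp1 (-0.82 ± 0.16) passed over all genes, and 8 members did when adjusted over the list alone. Cldn2 stood at 152 ± 14.8 and 149 ± 16.8 FPKM in flox and CKO NEC tissue, where in control the values were 81.8 ± 12.9 and 172 ± 17.6. Mitochondrially encoded genes rose (median of 1.03, 13 of 13 members above 0, adjusted p = 4.52e-08, and 1.00 with an estimated correlation), with 11 past the threshold adjusted over the list alone and 0 over all genes. Genes of Ca2+ and CaMKII signalling fell (median of -0.26, 24 of 30 members below 0, adjusted p = 0.0259, and 1.00 with an estimated correlation), with 4 members past the threshold adjusted over the list alone. These 4 include the calcineurin subunit Ppp3r1 (21.1 ± 4.53 and 36.3 ± 4.70 FPKM in flox and CKO control, 36.5 ± 1.57 and 35.7 ± 4.56 in NEC) and the endoplasmic reticulum Ca2+ sensor Stim2 (4.12 ± 0.427 and 6.13 ± 0.702 in control, 8.06 ± 0.296 and 7.59 ± 0.775 in NEC). The Ca2+ and CaMKII list was lost without CKO control library 3 (adjusted p = 0.104), CKO NEC library 1 (0.0898), flox control library 2 (0.0637) or flox NEC library 3 (0.0787).

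Among the named genes past the threshold with a more negative difference in NEC, Hnf4g had an interaction of -1.42 ± 0.20 SE (adjusted p = 0.0367) and the interleukin-22 receptor gene Il22ra1 one of -1.59 ± 0.30 (adjusted p = 0.0441). Il22ra1 stood at 10.2 ± 2.52 and 29.7 ± 3.31 FPKM in flox and CKO control tissue and at 37.6 ± 4.16 and 35.1 ± 9.37 FPKM in NEC. The copper transporter Atp7a, the protease inhibitor Timp3, the junction receptor Cxadr and Fam83b, Sacm1l, Pstpip2, Garem1 and Rnf125 had interactions between -1.64 and -1.30. Among those with a more positive difference, the apolipoprotein Apoc1 stood at 5.15 ± 0.631 and 2.46 ± 0.467 FPKM in flox and CKO control tissue and at 0.573 ± 0.0800 and 1.29 ± 0.0839 FPKM in NEC (1.38 ± 0.18 SE, adjusted p = 0.0367). The signalling ligand Wnt4, the chemokine Ccl27a, the electron carrier subunit Etfb and Fendrr, Bola2, Rpp21, Fbxl6 and Lsmem2 had interactions between 0.93 and 1.79. Mir7213 passed too, at 3.92 ± 2.40 and 0.408 ± 0.706 FPKM in flox and CKO control tissue and 1.13 ± 0.0993 FPKM in CKO NEC tissue, and was listed at 0 in the flox NEC libraries. These values rest on very few reads per library. The cell death genes Bax (1.13 ± 0.26, adjusted p = 0.0594) and Pycard (0.83 ± 0.20, adjusted p = 0.0641) and the cytokine genes Ccl20 (-0.38 ± 0.29) and Il33 (-0.31 ± 0.25) did not pass.

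In the interaction, 3082 genes had an unadjusted p under 0.05 and limma-voom called 126 genes. Of 31 lists tested, 1 rose and 2 fell, and 0 did so with an estimated correlation. In the mechanosensitive and sex-linked lists, which did not pass, the median, the mean and the direction of the test differed in sign. The count of 181 genes became 646 without flox control library 3, 307 without CKO control library 3, 28 without CKO NEC library 3 and 0 to 2 without any other single library. It was 24 with equal medians, 44 without a variance trend, 41 without a filter or with the length trend removed, 417 with a mean FPKM of 5 or more, 973 with array weights and 1 with sex as a covariate. With the mitochondrial share as a covariate limma called 0 genes (575 at an unadjusted p under 0.05; limma-voom without it 126). The mitochondrial and junction lists stayed past the threshold without any one library.

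The levels in NEC and in control tissue, which bear on what NEC does to the bowel, are set side by side here with no test, because each condition has a table of its own whose libraries had been scaled separately. NEC values sit on average 0.15 log2 higher than they would with one scaling for all 12 libraries. Condition cannot be told apart from the table or a shared batch. NEC tissue held lower levels of transcripts of the suckling intestine, of interferon-stimulated genes, of B cells and of the mitochondrial genome. It held higher levels of transcripts of dividing cells, of goblet and Paneth cells, of matrix and of epithelial defence. Of 13 suckling enterocyte genes, 11 in flox and 12 in CKO lay lower in all 3 NEC libraries than in all 3 control libraries. The protease gene Ctsl stood at 386 ± 165 FPKM in flox control and 28.3 ± 2.62 in flox NEC tissue, Fcgrt at 767 ± 272 and 89.8 ± 14.98, and lactase, Lct, at 114 ± 49.9 and 20.2 ± 8.68. The sucrase-isomaltase gene Sis, typical of the weaned intestine, stood at 0.858 ± 0.246 FPKM in flox control and 123 ± 54.6 in flox NEC tissue, and in CKO at 1.13 ± 0.208 and 70.5 ± 49.2. Of 15 interferon-stimulated genes, 14 in flox and 11 in CKO lay lower in all NEC libraries, such as Isg15 (64.6 ± 12.9 FPKM in flox control and 0.874 ± 0.497 in flox NEC) and Irf7 (80.7 ± 5.29 and 6.12 ± 1.80). Of 8 B and plasma cell markers, 3 in flox and 8 in CKO lay lower, and of 13 mitochondrially encoded genes 12 and 9.

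Of 21 cell cycle genes, 20 in flox and 21 in CKO lay higher in all NEC libraries than in all control libraries, such as cyclin B, Ccnb1 (1.93 ± 1.151 FPKM in flox control and 13.4 ± 1.05 in flox NEC). Of 12 stem cell markers, 7 and 10 lay higher, such as Lgr5 (0.571 ± 0.163 and 3.26 ± 0.818 FPKM in flox). Goblet cell markers lay higher in 8 and 5 of 9 and Paneth cell markers in 7 and 6 of 11, such as Spink4 (16.7 ± 8.80 and 227 ± 36.3 FPKM in flox), Defa24 (27.7 ± 16.8 and 272 ± 13.99) and matrilysin, Mmp7 (0.960 ± 0.675 and 19.1 ± 1.44). Epithelial antimicrobial genes lay higher in 8 and 10 of 11, such as the immunoglobulin transporter Pigr (8.41 ± 2.08 and 72.3 ± 14.4 FPKM in flox), and the secreted scavenger receptor Dmbt1 stood at 1.71 ± 0.517 and 143 ± 32.2. Fibroblast and matrix genes lay higher in 11 and 12 of 12, endothelial markers in 8 and 8 of 9, and smooth muscle genes in 9 and 1 of 10. Mechanosensitive channels lay higher in 9 of 10 measured in flox and 7 of 8 in CKO, such as Piezo1 and Tmem63b (9.08 ± 0.759 and 23.1 ± 1.62 FPKM in flox). Of the Ca2+ and CaMKII genes, 16 of 30 in flox lay higher and 3 lower, and 11 and 6 of 29 did in CKO. Of 4 inflammatory cytokine genes measured in each genotype, 1 lay higher and 1 lower. Chance gives 10% of genes whose 3 and 3 values do not overlap, but of all genes measured 38.5% lay higher and 26.0% lower in all NEC libraries in flox, and 32.2% and 21.6% in CKO, so these tallies are to be read against those shares.

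**Figure D4:**
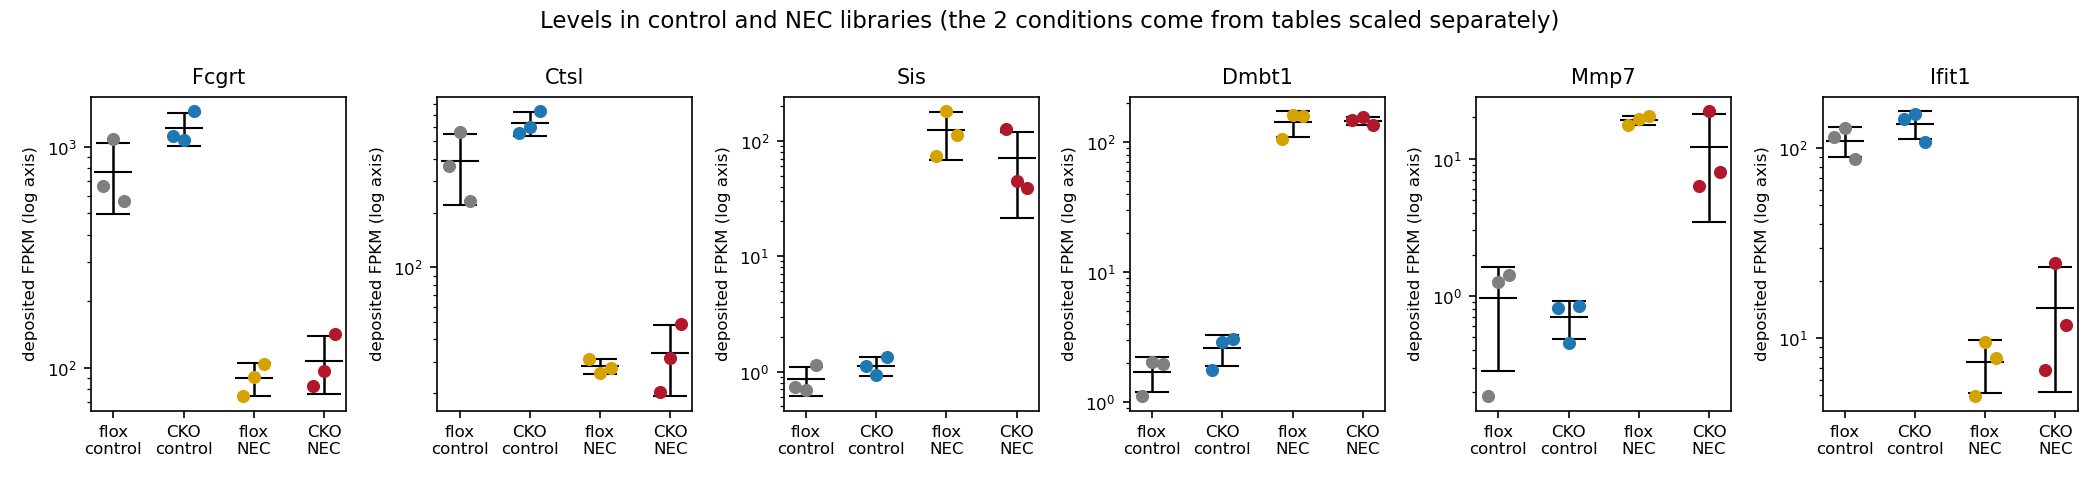
Deposited FPKM on a logarithmic axis of 2 suckling enterocyte genes (Fcgrt, Ctsl), Sis, Dmbt1, the Paneth gene Mmp7 and the interferon-stimulated gene Ifit1 in the 12 libraries, with points for libraries and bars for the mean and SD. The 2 conditions come from tables scaled separately, and Sis averages 0.858 FPKM in flox control and 123 FPKM in flox NEC libraries.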

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

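The tests on gene length, on the scaling of the libraries, the 2 on Piezo1 and the 20 assignments within NEC were chosen only after the result was seen, and the others in this part before.

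The genotype change differed between NEC and control in the interaction test for 181 genes and 3 lists. The named genes whose change was more negative in NEC were Timp3 (-1.64), Il22ra1 (-1.59), Atp7a (-1.52), Fam83b (-1.50), Sacm1l (-1.47), Pstpip2 (-1.46), Hnf4g (-1.42), Garem1 (-1.41), Rnf125 (-1.32), Cxadr (-1.30), Cldn2 (-1.09), Ocln (-1.06) and Tjp1 (-0.82), on the log2 scale. Those whose change was more positive were Mir7213 (2.85, fitted from very few reads and from flox NEC libraries listed at 0), Lsmem2 (1.79), Apoc1 (1.38), Fendrr (1.12), Bola2 (1.11), Etfb (1.07), Rpp21 (1.04), Wnt4 (1.04), Ccl27a (0.98) and Fbxl6 (0.93). The lists were the junction genes (median of -0.50), the Ca2+ and CaMKII genes (-0.26) and the mitochondrially encoded genes (1.03). When genotype was reassigned within each condition, 3 of 100 splits, the real one included, gave as many genes (highest other 520), but most of those splits also break up the control genotypes. With the real genotypes kept in control, 5 of the 20 assignments of genotype among the NEC libraries gave as many genes and the highest other gave 898, so chance in the grouping of the NEC libraries is not excluded for the gene count. The 898 came from setting flox NEC libraries 1 and 3 with CKO NEC library 1, and a structure among the NEC libraries was not tested. That assignment also gave 4148 genes at an unadjusted p under 0.05, beside 3082 for the real one. For the lists, 97 of 100 splits gave at least 3 and the highest other gave 20, so chance is not excluded for them.

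The control difference is the first pattern weighed: mitochondrially encoded transcripts and many other genes differed by genotype in control, with 3849 genes at an unadjusted p under 0.05. Removing a GC trend from each library left 3648 such genes and a mitochondrial median of -1.10, removing a gene length trend left 3570 and a median of -0.91, and equal library medians left 3784 and a median of -1.05, all of which argue against these trends as the whole cause. The highest number at an unadjusted p under 0.05 among the other 9 splits of the 6 libraries was 1486. For the counts past the adjusted threshold the splits are too few for a share under 0.05: 1 of 10 gave as many genes as the real split (1, highest other 0) and 7 of 10 as many lists (9, highest other 12). A difference in handling or in litter between the genotypes, which the labels do not give, stays open as untested, and so does an effect of Piezo1 loss, which may lie behind the difference but cannot be told apart from them.

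Lower Piezo1 in the CKO NEC libraries is the second pattern weighed. It could come from a smaller share of stromal cells, which also express Piezo1, or from its loss in the epithelium. The stromal genes tested had a median of -0.37 and 31 of 31 were below 0. Without CKO NEC library 3 that median was -0.19 beside -0.32 for Piezo1, so the NEC values do not decide for or against a stromal share. In control the stromal median was -0.64 beside -0.06 ± 0.19 SE for Piezo1. There Piezo1 did not follow the stromal genes, though it lay near 1 FPKM. An epithelial loss in either condition would lower Piezo1 in control too. The difference between the conditions was -0.46 ± 0.25 SE, within 2 SE of 0. Since 1 was added to the FPKM, an equal proportional loss would give a smaller change in control, where Piezo1 lay near 1 FPKM. A comparison with 0 is thus not exact, and an epithelial loss stays open as well.

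For CKO against flox in NEC the splits are too few for a share under 0.05. All 10 gave as many genes as the real split by limma (0, with 599 at an unadjusted p under 0.05 and 0 by limma-voom, highest other 7), and 1 of 10 gave as many lists (15, highest other 14). At an unadjusted p under 0.05, 4 of 10 splits, the real one included, gave at least 599 genes, and the highest other gave 1079.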

How the results depend on the processing

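The alternatives chosen only after the data were seen were limma-voom, protein-coding genes alone, the covariates for sex and mitochondrial read share, removal of a gene length trend, and every test on jointly rescaled reads. The reversal test that had been planned on deposited values was not run. The planned test of NEC against control was run on them only as an alternative to the joint rescaling. The filter on a mean FPKM of 5 gave no value for Piezo1 in control. Where a count moved, the cause was not tested, unless fewer libraries or other genes tested are part of the alternative.

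In NEC, 0 genes passed by limma under 17 of 20 alternatives (599 at an unadjusted p under 0.05, limma-voom 0), and 1 passed without flox NEC library 3 (Gm45774), CKO NEC library 1 (Defa21) or CKO NEC library 3 (Gapdh), a range of 0 to 1. The 15 lists became 0 with the estimated correlation and stayed between 10 and 17 under the 20 others, with 10 without flox NEC library 3 or CKO NEC library 1. Piezo1 stayed lower under all 20 (-0.64 to -0.32, adjusted p of 0.570 to 1.00). With the replicate number as a block, the counts were 0 genes and 14 lists in NEC, 903 genes and 9 lists in control, and 170 genes (126 shared with the 181) and 5 lists in the interaction. In control the values showed such a pairing only between the libraries numbered 3.

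In control, the count of 1 gene became 0 without a filter, with the gene length trend removed or with the mitochondrial share as a covariate, 23 with limma-voom, 441 with protein-coding genes alone, 760 with the mean FPKM of 5, 2051 with all 4 groups in the fit and 2200 with array weights. It ran from 0 to 830 when 1 library was left out, with 830 without flox control library 3. The next adjusted p, 0.0547, was shared by 295 genes, so a small move of the adjusted p changes the count. The 9 lists became 0 with the estimated correlation and kept within 1.5 times that number under the 20 others. Piezo1 reversed with quantile normalization (0.037) and without CKO control library 3 (0.031), in a range of -0.22 to 0.031 when 1 library was left out.

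In the interaction, the 181 genes became 41 without a filter, 417 with the mean FPKM of 5, 24 with equal medians, 44 without a variance trend, 973 with array weights, 1 with sex, 41 with the length trend removed and 0 by limma with the mitochondrial share (575 at an unadjusted p under 0.05; limma-voom without it 126). They ran from 0 to 646 when 1 library was left out, with 646 without flox control library 3, 307 without CKO control library 3 and 28 without CKO NEC library 3. The 24 genes with equal medians and the 44 without a trend were all among the 181, and the 973 with array weights held all 181. The 3 lists became 6 without a filter, 5 with quantile normalization, 8 with array weights, 6 with limma-voom, 5 with sex, 8 with the mitochondrial share and 0 with the estimated correlation, and ran from 2 to 10 when 1 library was left out.

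Each list past the threshold within a condition or in the interaction kept the sign of its median with equal medians, quantile normalization, the length trend removed and limma-voom. Past the threshold no longer were oxidative phosphorylation in NEC (quantile 0.01, adjusted p = 0.769; length trend 0.04, adjusted p = 0.206), Ca2+ and CaMKII with the length trend removed in NEC (-0.04, adjusted p = 0.467) and in the interaction (-0.11, adjusted p = 0.204), and in control suckling genes with quantile normalization (0.36, adjusted p = 0.0722) and enteroendocrine genes with the length trend removed (-0.38, adjusted p = 0.129).

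For the jointly rescaled values, the genes past the threshold in flox became 4725 with the mean FPKM of 5 and 0 by limma with the mitochondrial share (1413 at an unadjusted p under 0.05), and those in CKO 3868 and 3633. The lists became 4 in flox and 8 in CKO with the mitochondrial share, and 0 in each with the estimated correlation. With values as deposited, limma called 8120 genes in flox (7114 shared with the 7835) and 6450 in CKO (5491 shared with the 6303). Piezo1 in flox lost its call with the mitochondrial share (1.56, adjusted p = 0.530, over a range of 4.93e-06 to 0.530). Leaving out 1 library gave 6730 to 7385 genes in flox and 4880 to 6226 in CKO.

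Named genes reversed as follows; the cause was not tested, but the mitochondrial share nearly follows genotype in control and condition in flox, so a fit with both has little left to part them. In NEC, Camk2d was 0.069 with the length trend removed. In control, Camk2b was -0.019 with sex, -0.0082 with the length trend removed, -1.52 with the mitochondrial share, -0.019 without flox control library 1 and -0.19 without CKO control library 3 (range of -0.19 to 0.40 when 1 library was left out), and Lif was 0.029 with sex or without flox control library 1. With the mitochondrial share in control, Lif was 1.02, Camk2d -0.060, Mttp -0.48, Dpp4 -0.23, Fcgrt -0.98, Ctsl -0.75, Pyy 0.20 and mt-Co2 0.23. In the interaction, Camk2b, at -0.0036, was 0.0043 with a pseudocount of 0.1, 0.034 with equal medians, 0.12 with array weights, 0.019 with limma-voom, 0.20 with the length trend removed, 1.49 with the mitochondrial share, 0.17 without flox control library 1, 0.34 without CKO control library 3, 0.0069 and 0.032 without flox NEC libraries 2 and 3, and 0.0028 and 0.020 without CKO NEC libraries 1 and 2. Camk2d was 0.013 with the length trend removed, Camk2g -0.014 without flox control library 1 (range of -0.014 to 0.31), and Il33 0.084 and mt-Co2 -0.45 with the mitochondrial share. For NEC against control in flox, Camk2g was -0.033 with array weights, -0.13 with the length trend removed and -0.12 without flox control library 3, and Camk2b -0.16 with the length trend removed. With the mitochondrial share, Camk2b was -1.73, Zg16 -0.69, Clca4a -2.28, Defa24 -1.90, Lif 0.45, Cd79a 1.79, Cd79b 1.59, Igkc 2.32 and Kdr -0.25. In CKO, Camk2b was -0.23 with the mitochondrial share and -0.048 without CKO control library 2 (range of -0.048 to 0.54). Other values of named genes kept their direction: in NEC 1364 of 1365, in control all but 15 of 1061 (173 of them newly past the threshold) and in the interaction all but 16 of 961 (354 no longer past it and 18 newly past).

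Depth limits genes near 1 FPKM: Piezo1 in control lies there, and the cytokines other than 4 genes lay too low to be set side by side. On simulated data a log2 change of 0.5 was called for 20.9% of genes in NEC, 8.96% in control and 1.49% in the interaction, so changes of that size are mostly missed. Those genes had a mean FPKM of at least 5, so the shares do not cover genes near 1 FPKM.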

Other observations

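The tests of a more distal piece of intestine and of the overlap between genotypes were chosen only after the result was seen, and so was the joint rescaling of reads that every test in this part of NEC against control rests on; the tests of a glucocorticoid response, of the tables and of a reversal were set before their results were seen.

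With reads rescaled over all 12 libraries, NEC tissue differed from control tissue in both genotypes. The lists past the threshold in both included suckling enterocyte, cell cycle, goblet cell, Paneth cell, interferon-stimulated and B and plasma cell genes. By limma, 3969 genes rose and 3866 fell in flox and 2948 and 3355 did in CKO, of 14609 tested. Piezo1 rose in both genotypes (1.68 ± 0.17 SE in flox, adjusted p = 2.49e-05; 1.24 ± 0.17 in CKO, adjusted p = 3.60e-04), and so did Camk2d (0.71 ± 0.16, adjusted p = 0.00356; 0.44 ± 0.16, adjusted p = 0.0474). The 3 NEC libraries lay above the 3 control libraries for Piezo1 in each genotype. Sis (5.82 and 4.73), Dmbt1 (5.57 and 5.24) and Spink4 (3.63 and 3.81) rose in flox and CKO, while Isg15 (-5.22 and -3.61), Ctsl (-3.79 and -4.41), Fcgrt (-3.19 and -3.65) and Smcp (-6.43 and -5.48) fell. Paneth markers (median of 2.57 in flox and 1.76 in CKO) and cell cycle genes (1.27 and 1.56) rose, and suckling enterocyte genes (-1.75 and -2.09), interferon-stimulated genes (-1.90 and -1.53), B and plasma cell markers (-1.79 and -2.14) and mitochondrially encoded genes (-2.01 and -0.95) fell. In flox 12 of 31 lists passed and in CKO 13, at adjusted p of 0.767 in flox and of 0.326 to 0.791 in CKO with an estimated correlation. The splits are too few for a share under 0.05: in flox 1 of 10 gave as many genes (7835, highest other 1) and 5 of 10 as many lists (12, highest other 13), and in CKO 1 of 10 as many genes (6303, highest other 1) and 1 of 10 as many lists (13, highest other 12).

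The third pattern weighed is that suckling-type transcripts were lower and Sis, typical of the weaned intestine, was higher in NEC. The tables' scaling, 0.15 log2 apart on average, was removed by the joint rescaling. Under it Sis changed by 5.82 and 4.73 and Ctsl by -3.79 and -4.41, so scaling does not account for the pattern. The number of tables that hold libraries of both conditions is 0, so a batch that went with the table, of which the labels say nothing, cannot be told apart from NEC, and a difference in age stays open, untested. A more distal piece of intestine could also give it, but the distal genes had medians of -0.10 in flox and 0.54 in CKO beside -1.16 and -1.01 for the proximal genes, which leaves it open. A glucocorticoid response may be a candidate explanation: of 9 induced genes fixed after Fkbp5 and Sgk1 had been seen, the median was 1.12 in flox with 6 past the threshold upward, and 0.70 in CKO with 4 past it upward and Tsc22d3 downward, where 6 in each had been asked for, so it stays open.

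The change made by NEC in flox and the difference of CKO from flox in NEC were set against each other to ask whether CKO NEC tissue lies back toward control. Their covariance across 14609 genes, less the value simulated for the shared flox NEC libraries, was -0.0481 (SD of 100 simulated values 0.00147), and it was -0.0220 without CKO NEC library 3 and -0.0271 without flox NEC library 1. The correlation was -0.42, where sharing those libraries alone gave -0.50, and genes are not independent replicates. On an axis along the mean difference between the 6 NEC and the 6 control libraries, with the control mean at 0 and the NEC mean at 1 and each library part of its own axis, the flox NEC libraries scored 1.09, 1.04 and 1.04 and the CKO NEC libraries 1.03, 0.973 and 0.826. The difference of -0.11 had an exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. A partial move toward control may thus be present, carried in good part by CKO NEC library 3, which also had the lowest smooth muscle score.

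The same genes changed with NEC in both genotypes more often than independent lists would give, by a ratio of 2.85. The genes past the threshold in both numbered 2296 upward (801 by independent lists) and 2516 downward (888), and 22 went opposite ways. The changes in flox and CKO, which share no library, correlated at 0.83. Both lists come from the same fit with a shared spread per gene, so independent lists are a lenient yardstick. Both changes also follow the split of the tables, so a batch that went with the table cannot be told apart from NEC here either.

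Gm45774, Defa21 and Gapdh were singled out after their values were seen, since each passed in NEC when 1 library was left out. Gm45774, an antisense gene on chromosome 8, stood at 0.223, 0.304 and 24.3 FPKM in flox control, 10.3, 11.9 and 7.38 in CKO control, 0.384, 0.234 and 9.64 in flox NEC and 8.73, 7.65 and 9.06 in CKO NEC. Gapdh stood at 19.4, 24.5 and 1.79 FPKM in the CKO NEC libraries and at 1.45 to 2.08 in the flox NEC libraries. The alpha-defensin Defa21 stood at 23.4, 3.35 and 2.53 FPKM in CKO NEC and at 15.7 to 20.2 in flox NEC.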
